A study of Petromyzon marinus with 2 samples.

How the data were processed

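Olfactory epithelium was taken from free-living adult sea lampreys of 2 groups, reproductive and parasitic, with 1 library per group. Per the labels' protocols, 1 ug of total RNA went into SMART cDNA synthesis after an additional DNase treatment, followed by 13 cycles of long-distance PCR. The number of animals per library, the sequencing platform, the read length, the assembler and the read filters are not given in the sources used here. Neither is whether primer sequence of the cDNA kit was removed from the contigs. Library 1 of the deposited counts was taken as the reproductive and library 2 as the parasitic library, as the labels number them.

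The authors deposited, per the file headers, whole-number read counts of the 2 libraries for each of 28754 assembled contigs, each with its sequence, and these counts were used without rescaling. No count is normalised. Every contig holds at least 2 reads over both libraries, and reads outside contigs are not in the file, so the totals of 95826 and 88666 are reads in contigs rather than all reads sequenced. The sequences hold 783 bases other than A, C, G and T.

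The file does not pair its contigs with gene names. Of the 28754 contig IDs, 0 matched the table of 45433 reference genes, which holds no sequences. No contig was therefore given a gene name, none of the 26 gene lists fixed beforehand had a member, and the cell type markers taken from those lists could not be looked up. The rule for naming contigs was fixed before the data were examined. For contigs with no name, it takes the 2 called contigs in each direction whose 95% interval bound nearest to a ratio of 1 is farthest from it, and the 5 most abundant contigs of each library. The latter are described without IDs. Sequences are printed for those of them with at most 400 nt and reads in both libraries, a limit chosen after the data were examined. Sequences of contigs found in 1 library alone are not printed, because their organism could not be checked.

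The comparison of the libraries, its test and its thresholds were chosen before the data were examined. Each contig with at least 10 reads in all was tested with a two-sided Fisher's exact test of its reads against all other reads in contigs, with Benjamini-Hochberg adjustment over the tested contigs. A contig was called at an adjusted p of at most 0.05 and a ratio of at least 2 in either direction, and log2 ratios had 0.5 read added in each library. The test compares the 2 libraries and covers counting error only. Intervals are exact (Clopper-Pearson, for ratios conditional on the sum of the counts). A count of 0 was set against a floor of 3 reads.

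Contigs were joined into overlap groups by single linkage of all-against-all alignments with blastn 2.17.0, over at least 40 nt at 95% identity or more on either strand, or over at least 60 nt at 97% for a stricter version. The groups were added after the data were examined. Contigs that resembled a group were those that aligned to it over at least 30 nt at 85% identity or more. Opening bases of a contig were searched for with alignments of at least 16 nt. Repeats within a contig were counted as 12-base words that occurred more than once in it.

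The alternatives fixed beforehand were TMM and median-of-ratios scaling in an exact binomial test, other minimum counts, other minimum ratios, other prior counts, leaving out the 10 most abundant contigs of each library, thinning the deeper library, detection at 3 reads and the share of the 50 most abundant contigs. TMM factors, median-of-ratios factors and a negative binomial exact test with assumed coefficients of variation of 0.4 and 0.2 were written for this work rather than taken from edgeR or DESeq2. The alternatives added after the data were examined were this negative binomial test, in place of the planned one of that kind, median-of-ratios factors over contigs of 10 or more reads, overlap groups, leaving out contigs shorter than the median and leaving out contigs found in 1 library alone. The median-of-ratios factors over all contigs with reads in both libraries were both 1, because 5578 of those 12278 contigs held as many reads in each library. The version over contigs of 10 or more reads also used only contigs with reads in both libraries. Its factors were 1.22 for the reproductive and 0.816 for the parasitic library. It left out 212 contigs called higher in the parasitic library and 109 called higher in the reproductive library.

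The methods were tested on simulated counts for the comparison of the reproductive with the parasitic library, in which 200 contigs were changed and 2103 contigs held at least 10 reads. Fisher's exact test recovered 6 of 61 contigs changed 2-fold, 28 of 64 changed 4-fold and 55 of 66 changed 8-fold, and called 2 of 1912 unchanged contigs. The simulated counts varied by counting error only, so they do not show how many false calls amplified cDNA would give. The negative binomial test with a coefficient of 0.4 recovered 0 of the 66 changed 8-fold. In a simulated shift of composition over 28754 contigs, TMM recovered 1.04 of the true factor, median-of-ratios 1.16 over all contigs and 0.991 over contigs of 10 or more reads.

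Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used, with the random seed 7.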

Results

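Transcripts were compared between the olfactory epithelium of reproductive adult sea lampreys, caught on spawning habitat, and that of parasitic adults, which were attached to fish when they were caught. The comparison asks which transcripts of this tissue differ in abundance between the reproductive and the parasitic phase of adult life. Each phase was represented by 1 cDNA library, so no difference below has a replicate check. Phase also coincided with the season of capture, the habitat and the library, and all values compare these 2 libraries rather than the 2 phases. The measurement was the number of reads of each library in each of 28754 contigs, which are stretches of sequence assembled from reads of both libraries. The contigs held 95826 reads of the reproductive library and 88666 reads of the parasitic library. They were 49 to 1136 nt long, with a median of 126 nt, and 16850 of them held exactly 2 reads in all. The contigs carry numbers in place of gene names, so the values below belong to sequences whose genes are not given in the sources used here. All intervals are exact 95% intervals and cover counting error only, because reads of amplified cDNA are not independent molecules.

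The reproductive library had reads in 18214 contigs and the parasitic library in 22818, although the parasitic library held fewer reads in contigs. Both libraries had reads in 12278 contigs. The parasitic library alone had reads in 10540 contigs, and the reproductive library alone in 5936. After the reproductive library was thinned at random to the 88666 reads of the parasitic one, a mean of 11059.5 contigs held parasitic reads alone and a mean of 5913 held reproductive reads alone, over 100 draws. Contigs of the parasitic library alone held 29649 of its reads, and contigs of the reproductive library alone held 17717.

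The 10 most abundant contigs of each library took similar shares of the reads, 13.1% of the reproductive library (12.9% to 13.4%) and 12.6% of the parasitic library (12.4% to 12.8%). The 50 most abundant contigs took 29.995% of the reproductive reads (29.7% to 30.3%) but 23.2% of the parasitic reads (22.9% to 23.4%). Accordingly, 327 contigs held 50% of the reproductive reads, against 1287 contigs for the parasitic reads.

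**Figure D1:**
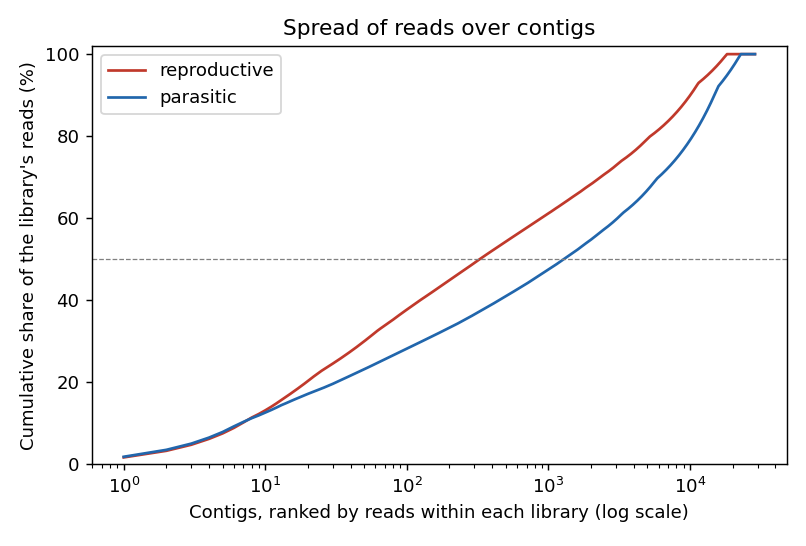
Cumulative share of each library's reads (y axis, percent) over contigs ranked by their reads within that library (x axis, log scale), 1 line per library. The lines cross 50%, the dashed line, at 327 contigs in the reproductive library and at 1287 contigs in the parasitic library.

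In all, 1939 contigs held at least 10 reads in both libraries together and were tested. They covered 65.6% of the reproductive reads and 51.8% of the parasitic reads. A two-sided Fisher's exact test on the reads, with Benjamini-Hochberg adjustment, called 827 contigs at an adjusted p of at most 0.05 and a ratio of at least 2. Of these, 441 were higher in the reproductive library and 386 were higher in the parasitic library, while 1112 tested contigs were not called. Under median-of-ratios scaling over contigs of 10 or more reads, the split was 289 higher in the reproductive library and 470 higher in the parasitic library. The factors of this scaling used only contigs with reads in both libraries, which left out more parasitic than reproductive calls. The contigs called higher in the reproductive library held 26.7% of its reads (26.5% to 27.0%) and 5.71% of the parasitic reads (5.56% to 5.87%). Those called higher in the parasitic library held 11.1% of its reads (10.9% to 11.3%) and 1.48% of the reproductive reads (1.40% to 1.56%). The contigs were picked by these same counts, so the direction of both contrasts follows from the calls. The intervals do not cover that choice. No parasitic read was found in 109 of the contigs called higher in the reproductive library, and no reproductive read in 212 of those called higher in the parasitic library.

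**Figure D2:**
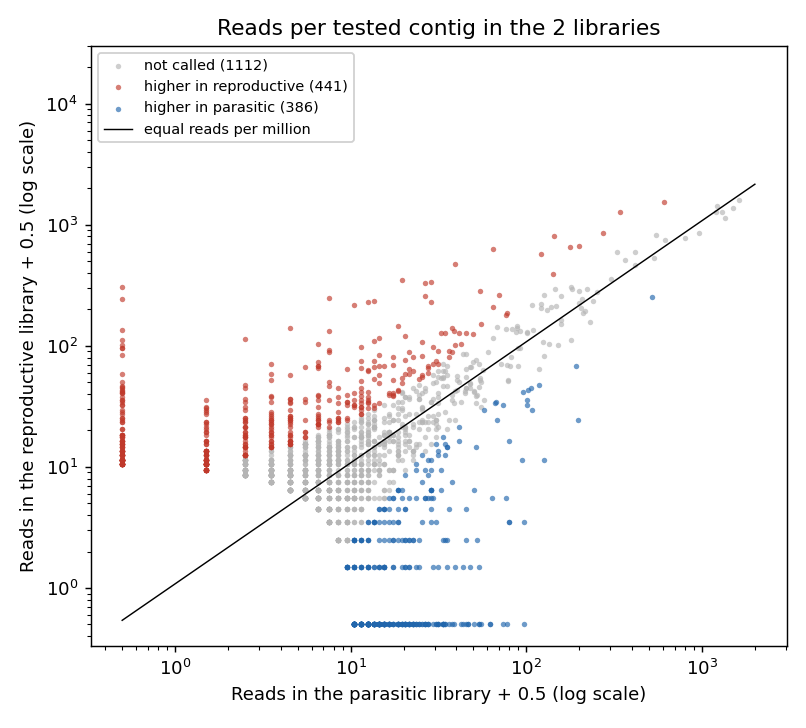
Reads of each tested contig in the parasitic library (x axis) and the reproductive library (y axis), both on log scales with 0.5 read added, 1 point per contig, coloured by call. The 441 contigs called higher in the reproductive library lie above the line of equal RPM, the 386 called higher in the parasitic library lie below it, and points at the axis value 0.5 have no read in that library.

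By the ranking fixed beforehand, the contigs with the strongest difference were short ones in the reproductive library and longer ones in the parasitic library. A count of 0 is read against a floor of 3 reads, which is 33.8 RPM (reads in a library scaled to 1000000 reads) in the parasitic library and 31.3 in the reproductive library. The contig Pem_ctig.18231, of 111 nt, held 308 reproductive reads (3214 RPM) and no parasitic read, so it was at least 94.996-fold higher in the reproductive library (adjusted p = 9.27e-86, Fisher's exact test). The contig Pem_ctig.23651, of 78 nt, held 242 reproductive reads and no parasitic read, at least 74.6-fold higher (adjusted p = 3.03e-67, exact test). In the other direction, Pem_ctig.6704, of 307 nt, held 97 parasitic reads (1094 RPM) and no reproductive read, at least 34.9-fold higher in the parasitic library (adjusted p = 9.85e-30, exact test). The contig Pem_ctig.5887, of 377 nt, held 77 parasitic reads and no reproductive read, at least 27.7-fold higher (adjusted p = 1.71e-23, exact test). These folds are against the floor of 3 reads. The exact intervals allow more reads behind a count of 0, and their lower bounds were 76.8, 60.2, 27.9 and 22.0. Both parasitic contigs belonged to the group of 499 overlapping contigs.

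The most abundant contigs were largely shared. Of the 10 most abundant contigs of each library, 8 were the same, and of the 5 most abundant, 3 were. The contig with the most reads in each library was the same one, of 770 nt, with 1600 reproductive and 1620 parasitic reads and a ratio of 0.914 for reproductive over parasitic RPM (0.852 to 0.980). Among the 5 most abundant contigs of the parasitic library, the ratios lay between 0.782 and 1.07 and none was called. The ratio of 1.07, for a contig of 578 nt, became 0.771 under median-of-ratios scaling over contigs of 10 or more reads. Among the 5 most abundant contigs of the reproductive library, 2 were called higher in that library. A contig of 666 nt held 1286 reproductive and 340 parasitic reads, a ratio of 3.50 (3.10 to 3.96), and it was 2.52 under the same other scaling. A contig of 124 nt held 1544 reproductive and 610 parasitic reads, a ratio of 2.34 (2.13 to 2.58). Its ratio was 1.69 under the other scaling, below the minimum of 2. Its first 25 bases were found in 16 contigs of 11 overlap groups, and 12 of these contigs lay outside its own group. Bases 26 to 50 were found in 210 contigs of 2 groups, 1 contig of them outside its own group. For bases 51 to 75 it was 329 contigs of 4 groups, 3 of them outside. For bases 76 to 100 it was 314 contigs of 13 groups, 69 of them outside. Whether the opening bases are primer sequence of the cDNA kit is not given in the sources used here. The sequence of this contig was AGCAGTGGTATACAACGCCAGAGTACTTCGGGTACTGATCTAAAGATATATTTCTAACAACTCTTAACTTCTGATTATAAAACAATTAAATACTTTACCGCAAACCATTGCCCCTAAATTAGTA.

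The 7 contigs among the 5 most abundant of either library included 3 of at most 400 nt. Besides the contig of 124 nt, these were a contig of 354 nt with 1371 reproductive and 1498 parasitic reads, and a contig of 337 nt with 1281 and 1296 reads. The first had the sequence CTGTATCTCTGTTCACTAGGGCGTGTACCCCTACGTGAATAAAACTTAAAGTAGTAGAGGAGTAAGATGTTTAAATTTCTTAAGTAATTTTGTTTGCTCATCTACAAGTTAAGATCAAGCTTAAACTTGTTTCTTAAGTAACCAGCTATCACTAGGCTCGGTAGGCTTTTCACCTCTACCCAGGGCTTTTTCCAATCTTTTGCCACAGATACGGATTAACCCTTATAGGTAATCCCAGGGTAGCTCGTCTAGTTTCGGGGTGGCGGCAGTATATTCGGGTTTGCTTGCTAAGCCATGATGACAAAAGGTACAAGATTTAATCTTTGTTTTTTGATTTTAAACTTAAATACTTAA. The second had the sequence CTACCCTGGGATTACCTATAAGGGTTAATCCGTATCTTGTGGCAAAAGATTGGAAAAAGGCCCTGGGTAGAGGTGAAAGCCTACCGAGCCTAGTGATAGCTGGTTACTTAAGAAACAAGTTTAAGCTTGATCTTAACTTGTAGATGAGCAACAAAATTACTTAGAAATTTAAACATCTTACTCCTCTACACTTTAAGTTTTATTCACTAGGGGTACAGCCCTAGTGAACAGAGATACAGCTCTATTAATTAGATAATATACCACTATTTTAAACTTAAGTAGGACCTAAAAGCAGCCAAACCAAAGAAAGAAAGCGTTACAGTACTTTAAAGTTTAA. The pair aligned to each other over 245 nt at 96.7% identity on opposite strands, so closely similar sequence stood in separate contigs. Over the whole set, 13665 contigs overlapped another contig by at least 40 nt at 95% identity or more, and 9613 of them did so on the opposite strand.

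Contigs that overlapped in this way were therefore also joined into groups, and the reads of each group were summed. This gave 16888 groups, of which 1799 held more than 1 contig, and 883 groups held at least 10 reads. The same exact test called 146 groups higher in the reproductive library and 140 higher in the parasitic library. Groups with reads of the parasitic library alone numbered 6769, against 3132 for the reproductive library. The group with the most contigs, 2968, took 37.7% of the reproductive and 30.8% of the parasitic reads, a ratio of 1.23 (1.21 to 1.25), which became 0.884 under median-of-ratios scaling over contigs of 10 or more reads. A group of 423 contigs held 6524 reproductive and 671 parasitic reads and was 8.996-fold higher in the reproductive library (8.31 to 9.75). A group of 154 contigs, with 2684 and 656 reads, was 3.79-fold higher in that library (3.47 to 4.13). In the other direction, a group of 2000 contigs held 1972 reproductive and 7964 parasitic reads and was 4.36-fold higher in the parasitic library (4.15 to 4.59). A group of 499 contigs held 2 reproductive and 2854 parasitic reads, or 3.22% of the parasitic library, a ratio of parasitic over reproductive of 1542 (427 to 12741). A group of 89 contigs held 513 parasitic reads and no reproductive read, at least 185-fold higher in the parasitic library against the floor (lower bound of the interval, 150). The ratios depended on the overlap required. Under the stricter overlap, the largest group inside the one of 2968 had 1148 contigs and a ratio of 1.01 (0.987 to 1.03). The excess in the reproductive library was not seen in that part. Another stricter group, of 299 contigs with 6604 reproductive and 1737 parasitic reads, was 3.52-fold higher in the reproductive library (3.34 to 3.71). It also lay inside the one of 2968, as no other overlap group had as many contigs and reproductive reads. The largest inside the one of 423 was 12.4-fold higher in the reproductive library (11.2 to 13.7), and that inside the one of 154 was 4.23-fold higher (3.82 to 4.70). The largest inside the one of 2000 was 7.47-fold higher in the parasitic library (6.71 to 8.34), and that inside the one of 499 held 1 reproductive and 2186 parasitic reads. A group's ratio is a sum over contigs that need not go the same way. Contigs called in both directions stood in 12 groups, which held 209 of the 441 contigs called higher in the reproductive library and 178 of the 386 called higher in the parasitic library. The group of 2968 contigs held 73 and 31 of these, the group of 2000 held 12 and 119, and the group of 423 held 77 and 1.

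**Figure D3:**
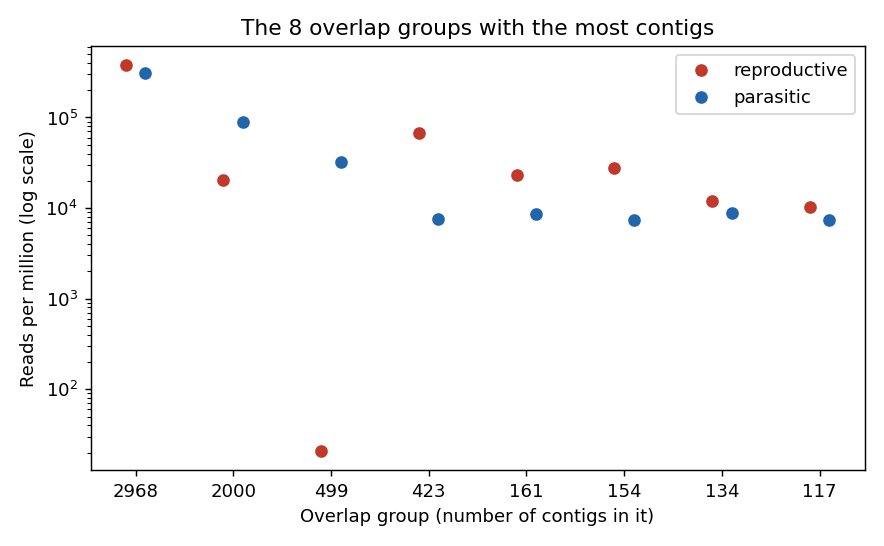
Summed reads, in RPM (y axis, log scale) of the 8 overlap groups with the most contigs (x axis, labelled by their number of contigs) in each library, 1 point per library. The group of 499 contigs stands apart, with 20.9 RPM in the reproductive library against 32188 in the parasitic library.

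Contigs with at least 30 reads that were found in 1 library alone differed in length between the libraries. The 24 found in the reproductive library alone had a median length of 101 nt, and 21 of them (87.5%, 67.6% to 97.3%) were shorter than the median contig. The 29 found in the parasitic library alone had a median length of 270 nt, and 1 of them was shorter than the median contig (3.45%, 0.0873% to 17.8%). Of the 527 found in both libraries, with a median of 268 nt, 12.9% (10.2% to 16.1%) were shorter. The 24 contigs fell into 17 overlap groups and the 29 into 8, so these contigs are not independent and the intervals, which treat them as such, are too narrow.

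**Figure D4:**
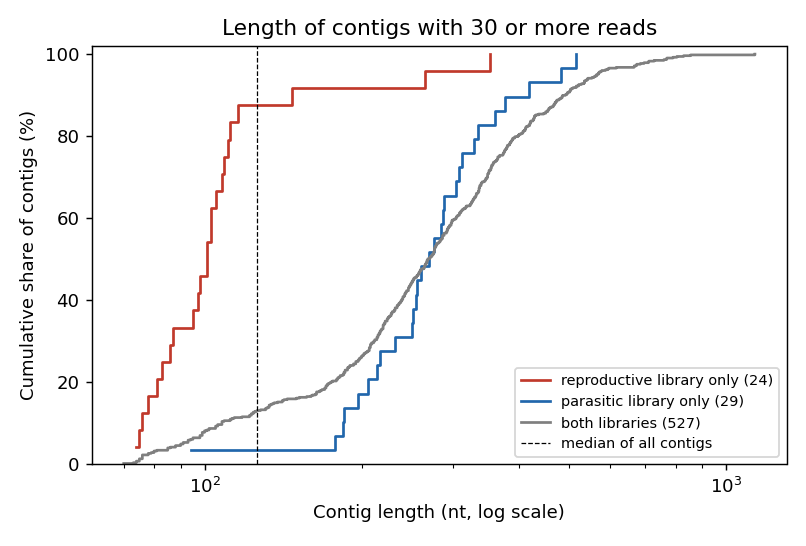
Cumulative share (y axis, percent) of contigs with 30 or more reads by their length (x axis, nt, log scale), 1 line each for contigs with reads in the reproductive library alone, in the parasitic library alone and in both. At the median length of all contigs, 126 nt, marked by the dashed line, the reproductive line has reached 87.5% and the parasitic line 3.45%.

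The ratio also varied with base composition and contig length, across contigs, which are not replicates. The tested contigs were sorted into 5 bins of equal size by GC content. From the lowest to the highest GC content, the median log2 ratio of reproductive over parasitic was 0.25, 0.07, -0.11, 0.42 and 0.96, so it did not rise throughout. Sorted by length in the same way, it was 0.92 in the bin with the shortest contigs and lay between 0.09 and 0.32 in the other bins. Median-of-ratios scaling over contigs of 10 or more reads lowers each of these values by 0.47, which leaves the bin with the highest GC content and the bin with the shortest contigs as the only ones above 0. Contigs in which at least 50% of the 12-base words occurred more than once numbered 592. They took 2.13% of the parasitic reads (2.04% to 2.23%) and 0.800% of the reproductive reads (0.745% to 0.859%), and were 2.66-fold higher in the parasitic library (2.45 to 2.90). They made up 23 of the 386 contigs called higher in the parasitic library, 4 of the 441 called higher in the reproductive library and 20 of the 1112 not called. Some shared an overlap group, so they are not independent and the intervals are too narrow. A group of 62 contigs, with 4 reproductive and 358 parasitic reads, held 37 of them. A group of 101 contigs, with 244 and 322 reads, held 27.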

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

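The negative binomial test, median-of-ratios factors over contigs of 10 or more reads, overlap groups and leaving out short contigs or contigs of 1 library were tried only after the data were examined.

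The 827 calls (441 higher in the reproductive library, 386 higher in the parasitic library) stayed between 588 and 878 in all under TMM or median-of-ratios scaling, no minimum count, other minimum ratios, leaving out abundant or short contigs, thinning, and a negative binomial test with an assumed coefficient of variation of 0.2. With no minimum count, the calls were 279 higher in the reproductive library and 309 higher in the parasitic library. At least 30 reads per contig left 308 calls (205 and 103), because fewer contigs were tested. A coefficient of 0.4 left 280 (119 and 161), and leaving out contigs of 1 library left 470, of which 162 were higher in the parasitic library, as this takes out 212 of the 386 parasitic calls and 109 of the 441 others, and the adjustment then runs over fewer contigs. Summed by overlap group, 286 groups were called (146 and 140), or 400 (198 and 202) under the stricter overlap, since several contigs then counted once.

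Which direction held more calls changed with the processing. The share of calls higher in the reproductive library was 53.3% as reported, 55.2% under TMM and 66.6% at 30 or more reads. It was 38.1% under median-of-ratios factors over contigs of 10 or more reads (289 such calls), 42.5% at a coefficient of 0.4, 47.3% without short contigs, 47.4% with no minimum count and 48.5% at a ratio of at least 4. The median log2 ratio of tested contigs was 0.32, and was 0.43 under TMM and 0.44 under median-of-ratios scaling over all contigs. It was -0.15 under median-of-ratios scaling over contigs of 10 or more reads. That scaling sets the median ratio of tested contigs with reads in both libraries to 1. Among the calls, 212 contigs had no reproductive read and 109 no parasitic read. A median of about 0 or below was therefore fixed beforehand, and the change of sign is no check on the 0.32. Contigs with as many reads in each library, 4887 of them with 1 read in each, set the median-of-ratios factors over all contigs. TMM also used the contigs with reads in both libraries and gave nearly the same value, so it is not an independent check. How far such ties set the TMM factors, and what else lies behind the gap between these scalings, was not tested.

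Detection at 3 reads gave 5118 contigs in the reproductive and 5819 in the parasitic library, and overlap groups gave 10119 and 13756, with the parasitic library ahead each time. The 50 most abundant contigs took 29.995% and 23.2% of the reads. A prior of 5 reads shrank the log2 ratios of the 4 named contigs beyond the counting interval. Leaving out mitochondrial and ribosomal RNA, summing by gene name and the gene list alternatives were not run, since no contig has a name. Depth limits the calls, as a contig of 10 reads can show only large ratios.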

Other observations

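All tests below were chosen after the result they measure was seen, except the one that leaves out the 50 most abundant contigs of each library and the one that adds contigs resembling the group of 499.

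More contigs were found in the parasitic library alone than in the reproductive library alone. Depth counted as reads in contigs is argued against, since the parasitic library held 0.925 times the reads of the reproductive one. Reads outside contigs are not in the file, so depth in all reads sequenced could not be checked. A few abundant contigs are argued against as the whole cause, since the parasitic number was still 1.70 times the reproductive one (1.68 to 1.70 over 100 draws) without the 50 most abundant contigs of each library and at equal depth. With all contigs at equal depth, this factor was 1.87 (1.86 to 1.88 over the draws). Splitting over contigs that overlap by at least 40 nt is argued against too. Without thinning, the factor over overlap groups was 2.16, and it was 2.00 under the stricter overlap. Pieces of 1 sequence that do not overlap stay in separate groups, so splitting of that kind was not tested. A lower number of distinct cDNA molecules in the reproductive library and a difference between the phases, seasons or sites may each have produced it, and neither was tested.

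Contigs of 30 or more reads found in the reproductive library alone were short. Splitting over contigs that overlap by at least 40 nt is argued against. Other contigs of the same group held parasitic reads in 3 of the 16 overlap groups concerned that held any other contig (18.8%, 4.05% to 45.6%). Pieces of the same transcript that overlap the short contig by less than 40 nt, or not at all, could not be seen. Splitting of that kind stays open. Many copies of a few amplified molecules might give such stacks of short contigs. Of the other contigs in these groups, 6.52% (4.83% to 8.57%) started and ended within 10 nt of the deep contig. It was 0.0734% (0.00890% to 0.265%) in the 8 groups of such parasitic contigs, which held 2723 other contigs. These shares decide nothing, because group size sets them and 668 of the 721 contigs stood in the 3 groups that also held parasitic reads. In the groups without parasitic reads the share was 31 of 53 contigs (58.5%, 44.1% to 71.9%). Several of these contigs shared a group, so this interval is too narrow, and no matching share was computed for the parasitic contigs. Amplification, splitting without such overlap and a short transcript of the reproductive phase therefore cannot be told apart without the reads, and the short transcript was not tested.

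The group of 499 contigs had nearly all its reads in the parasitic library. Splitting by the assembly into contigs that resemble the group is argued against. The 30 contigs outside the group that resembled it held 5 reproductive and 65 parasitic reads. With them added, the ratio of parasitic over reproductive was 451 (218 to 1122). Pieces of the same transcript that share no stretch of at least 30 nt with the group would not be found in this way. Many copies of a few amplified molecules stay open, since 0 of its 65 contigs with 10 or more reads were shorter than the median contig, but only 16.5% of the other contigs at that depth were, and copies of longer molecules need not be short. This group was also among the 8 with a share of 0.0734% above. Reads from another organism could have entered a library of animals taken from fish, and the group's median GC content of 40.6% lay within the middle range of tested contigs that were not called (35.9% to 48.7%), which does not exclude it. Amplification, splitting without such a shared stretch, another organism and a difference of phase, season or site cannot be told apart here. No reference sequence was used here and 1 library stands for each phase.

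Over 494 contigs of 30 or more reads in 54 groups, the chi-square of their reads around the group's ratio was 13.5 per degree of freedom, and it was 7.97 under the stricter overlap. Both values set the spread against counting error alone, and reads of amplified cDNA are not independent, so they do not show that contigs of a group differ in ratio. If counts vary that far beyond counting error, the adjusted p values, calls and intervals above overstate their certainty.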
